A study of Picea abies with 36 samples.

How the data were processed

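Messenger RNA abundance was measured by RNA sequencing in hypocotyls, the stem below the cotyledons, of Norway spruce (Picea abies) seedlings grown for 2 weeks in a phytotron. Per the labels' protocols, lanolin with 135 mM BAP (6-benzylaminopurine, a cytokinin), 50 mM IAA (indole-3-acetic acid, the main natural auxin), both hormones, or a mock preparation was put on the hypocotyl a single time, and tissue was collected after 5, 10 and 15 days. The 36 libraries fell into 12 groups of 3. The labels do not say that the 3 replicates of a group came from separate plants or pools, so p-values measure only the spread between these libraries, which may be technical.

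The deposited values are raw read counts per gene model, whole numbers that the authors did not normalise. Trimmomatic, STAR and HTSeq are named in the submitters' processing notes, so reads were trimmed, aligned and counted per gene model, and no versions were given for them. The genome build, annotation and strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense gene models cannot be told apart, and models of near-identical paralogs may share or lose reads in the authors' counting. The table held 70736 gene models and no rows for unassigned reads. Its columns name the replicate, the hormone and a collection number from 1 to 3. That number was taken to follow the order of the collection days, which the table itself does not state, so every statement about a particular day rests on that reading, while the contrasts averaged over the 3 days do not. The files do not pair the gene model identifiers with gene names, so the gene lists fixed beforehand as name patterns could not be tested, and genes are described as groups and by a few identifiers.

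Counts were analysed in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Gene models were kept by edgeR's filterByExpr with the 12 groups, which left 38239 models tested and 32497 not tested, 18409 of them with no read in any library. The tested models held at least 99.89% of the reads of every library. Library sizes were scaled with TMM factors between 0.94 and 1.07. One quasi-likelihood model with 12 group means was fitted to all 36 libraries (24 residual degrees of freedom, robust dispersion), and contrasts were tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05, 2-sided. All adjusted p-values and counts of changed genes are from this model unless another tool is named. The contrasts were each hormone against same-day Mock, the mean of the 3 days against Mock and between hormones, the BAP by IAA interaction on each day (the log2 change of the combination minus the sum of the log2 changes of BAP and IAA), the effect at 15 days minus the effect at 5 days, and Mock over time. These contrasts, the main model, the rule for naming genes and the first set of alternatives were fixed before the data were examined.

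Normalised levels are given as CPM (read counts scaled to a common library size) computed here with the TMM-scaled library sizes, as mean and SD over 3 libraries. Fold limits of 2 and 16 and median folds were computed from pooled group levels, with a group level below 3 counts over the group set to 3 counts. A fold against a group without any read is therefore a lower bound. Library totals ran from 12531117 to 22280720 reads, so 3 counts in 1 library corresponded to 0.13 to 0.24 CPM. Such floors cover counting error only. Principal components used log2 CPM with a prior count of 2.

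Genes were named by a fixed rule. For each hormone, a gene had to pass the threshold in the mean of the 3 days, have the same sign on all 3 days, have every hormone library beyond every same-day Mock library on at least 2 days, and average at least 1 CPM over all libraries. Of these, the 2 with the largest log2 rise and the 2 with the largest log2 fall were named.

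The model was tested on simulated data drawn from the pooled Mock means, the library sizes and the dispersions, with 200 of 38239 genes changed. For BAP against Mock at 5 days it recovered 16.4% of 1.5-fold, 44.8% of 2-fold and 68.2% of 4-fold changes, with 2 wrong calls. For the mean of 3 days it recovered 47.8%, 80.6% and 89.4% at the same folds, with 6 wrong calls. For the interaction at 5 days it recovered 0%, 23.9% and 45.5%, with 0 wrong calls, and for the difference between the 15-day and 5-day BAP effects 4.5%, 32.8% and 53%, with 5 wrong calls. Differences of differences were thus read with less power than simple contrasts. The real contrasts called far more genes, 25.2% for BAP against Mock at 5 days. The adjusted threshold is less strict then, so these recoveries may not carry over to the real data.

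Comparisons that use the same Mock libraries share their chance values. Their overlap was set beside 10 simulations of unchanged groups against shared Mock libraries, and beside the overlap of independent lists. Alternatives were RLE size factors, total counts, no filter, a mean of at least 1 CPM, DESeq2 1.42.0 with the same group means, the replicate number as a block, fitting only the groups compared, and leaving out each library. Thinning all libraries to the smallest total, and a few further checks, were added after the data were examined. One of these permuted the residuals of a limma model on log2 CPM without the tested contrast, which leaves the treatment effects in place. Replicates of a group were compared for duplicates over models with at least 20 reads in the pair, and none were found. Figures were drawn with matplotlib 3.10.9.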

Results

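The transcriptome of the spruce hypocotyl was measured after local application of a cytokinin, an auxin or both, to find which genes each hormone moved, whether the response lasted, and how the combination compared with its parts. The 36 libraries, 3 for each of 4 treatments on 3 days, held 12531117 to 22280720 reads in gene models. Between 39948 and 42914 gene models had at least 1 read in a library. The 10 most abundant models took 3.8 to 5.8% of the reads.

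Libraries were arranged by treatment and day together, not by treatment alone. Replicates of a group correlated at r = 0.96 to 0.977 across genes, which are not independent replicates, and their counts differed by more than sampling noise (chi-square per degree of freedom 7.106 to 16.93). The first principal component held 32.2% of the variance and the second 22.6%. Mock libraries had the lowest group means on the first component at every collection, from -142 ± 13.5 (SD, n = 3) at 5 days to -127.7 ± 7.8 (SD, n = 3) at 15 days. IAA libraries moved on the second component from 29.7 ± 10 at 5 days to 144.3 ± 4.1 at 10 days and 141.8 ± 10.6 at 15 days (SD, n = 3). The combination stayed with BAP on that component, at -63.9 ± 5.8, -70.7 ± 4.8 and -69 ± 12.1 (SD, n = 3). On the first component BAP libraries went from -73.4 ± 21.3 at 5 days to 12.2 ± 20.2 at 15 days (SD, n = 3). The combination lay nearer to IAA than to BAP on that component, at 66.4 ± 12.7, 86.4 ± 11.4 and 107.2 ± 5.6 (SD, n = 3). IAA libraries were at 75.1 ± 11, 80.4 ± 7.6 and 68.3 ± 5.9 (SD, n = 3).

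**Figure D1:**
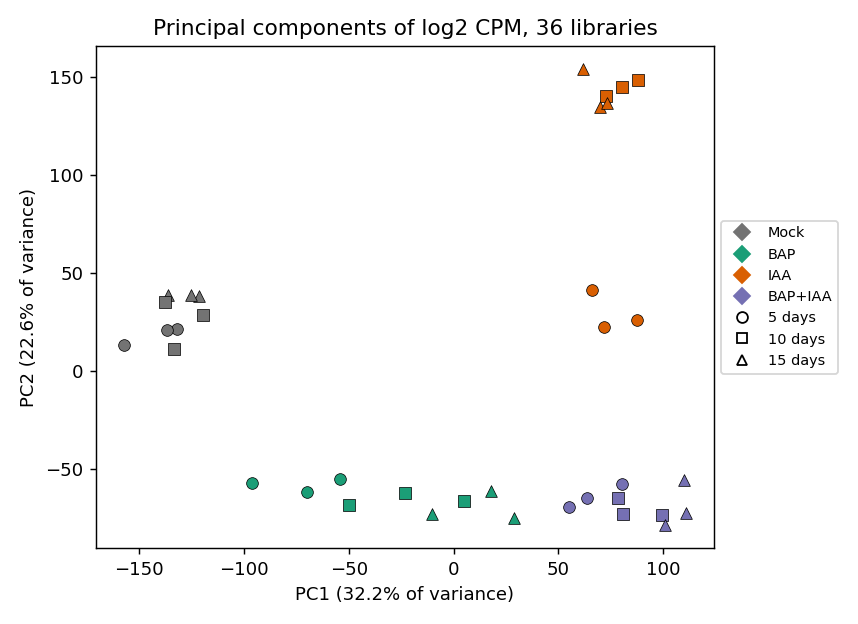
Each point is 1 of the 36 libraries, placed by its scores (no unit) on the first (x axis, 32.2% of variance) and second (y axis, 22.6%) principal components of log2 CPM, with colour for treatment and shape for day. IAA libraries of 10 and 15 days lie apart at the top, with group means of 144.3 and 141.8. The combination lies with BAP at the bottom on the second component, but nearer to IAA than to BAP on the first.

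Mock hypocotyls had 1 gene model that led all 9 of their libraries, with 1.27 ± 0.1% of reads at 5 days, 1.13 ± 0.12% at 10 days and 1.1 ± 0.093% at 15 days (SD, n = 3). This model was chosen after its values were seen. It fell under every treatment. Under IAA it held 0.154 ± 0.046% at 5 days, 0.216 ± 0.053% at 10 days and 0.389 ± 0.098% at 15 days (SD, n = 3). Under BAP it held 0.623 ± 0.12%, 0.552 ± 0.15% and 0.474 ± 0.068% on the same days (SD, n = 3). In the mean of the 3 days its log2 change was -1.18 ± 0.12 (SE) with BAP, -2.27 ± 0.13 with IAA and -2.31 ± 0.13 with both (edgeR adjusted p = 6.8e-09, 1.9e-14 and 8.5e-15).

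The comparison of BAP with Mock addressed the response to cytokinin alone. At 5 days 4275 genes were higher and 5344 lower, at 10 days 5424 and 6282, and at 15 days 6052 and 6348. The set with a rise of at least 16-fold held 66 genes at 5 days, 170 at 10 days and 539 at 15 days. Genes with a fall of that size numbered 82, 147 and 212. In the mean of the 3 days 9251 genes rose and 9833 fell. Which side held more genes depended on the scaling and, in part, on the filter and tool. With total counts in place of TMM factors, the rises and falls were 5502 and 4189 at 5 days, 6865 and 5203 at 10 days, 7692 and 5277 at 15 days, and 11547 and 8031 in the mean of the 3 days. At 15 days they were 6341 and 6120 with RLE size factors, and 6398 and 6037 with DESeq2. The gene model MA_488631g0010 was at 2.75 ± 1.24 CPM at 5 days, 16.2 ± 6.57 at 10 days and 5.41 ± 2.25 at 15 days with BAP (SD, n = 3). Mock had 2 reads of it over the 3 libraries at 5 days and none later, which made BAP at least 232-fold higher at 10 days and at least 81.4-fold higher at 15 days. With IAA no read of it was seen on any day, and with the combination it stayed at 0.206 ± 0.357 CPM or less (SD, n = 3), with reads in replicate 1 alone. MA_584053g0010 rose to 28 ± 16.3 CPM at 10 days (SD, n = 3; 1355 reads over the group; 18.6 CPM without replicate 2) where Mock had 3 reads over the group. Both were called in the mean of the 3 days (edgeR adjusted p = 3.5e-11 and 5.6e-10). MA_10313526g0010 fell 180-fold at 5 days and 309-fold at 15 days, from 26.8 ± 9.98 to 0.156 ± 0.0406 CPM and from 70.6 ± 37.1 to 0.235 ± 0.148 CPM (SD, n = 3; edgeR adjusted p = 6.8e-13 and 1.8e-16). MA_132857g0010 had no read in any BAP library, which was at least 43-fold below Mock at 10 days and at least 67.7-fold below it at 15 days (edgeR adjusted p = 0.032 and 0.01).

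Across all tested genes, log2 changes with BAP correlated at r = 0.70 between 5 and 10 days, 0.74 between 10 and 15 days and 0.64 between 5 and 15 days. These contrasts share no library. Of 7044 genes called at both 5 and 10 days, 99.9% had the same sign.

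The comparison of IAA with Mock addressed the response to auxin alone. IAA changed 18023 genes at 5 days, 15379 at 10 days and 13033 at 15 days. At 5 days 8824 were higher and 9199 lower, and at 15 days 6937 were higher and 6096 lower. Genes raised at least 16-fold numbered 698 at 5 days, 1030 at 10 days and 1077 at 15 days, while those lowered that far numbered 377, 209 and 95. In the mean of the 3 days 11455 genes rose and 10956 fell. Scaled by total counts, 10647 rose and 11752 fell in that mean, and 7130 rose and 8269 fell at 10 days, against 8158 and 7221 with TMM. The 5-day balance turned to 9057 and 9007 with RLE size factors and to 9198 and 8923 with DESeq2. MA_186946g0010 had no read in Mock at 5 and 10 days and stood at 17.4 ± 9.1 and 613 ± 80.5 CPM with IAA (SD, n = 3), at least 285-fold and at least 9060-fold higher. At 15 days it was 3430-fold higher, at 300 ± 88.8 CPM (SD, n = 3) against 4 reads over the Mock group. That fold rests on 1 library, since all 4 reads lay in replicate 1 of Mock, and without it the level was at least 2950-fold higher and the log2 change in the mean of the 3 days went from 12.97 to 14.16. In the combination it was at 3.41 ± 3.23 CPM at 10 days and 20.1 ± 27.5 CPM at 15 days (SD, n = 3), and without replicate 1 of the combination at 1.57 and 4.38 CPM. MA_4984597g0010 stood at 123 ± 50.1, 378 ± 90.5 and 143 ± 25 CPM on the 3 days (SD, n = 3), with 1, 0 and 1 reads over the Mock groups, and at 10 days it was at least 5550-fold higher. MA_10426531g0010 had no read in any IAA library, at least 99.4-fold below Mock at 5 days, at least 74.2-fold at 10 days and at least 53-fold at 15 days. MA_175194g0010 fell from 12.6 ± 3.3 CPM (SD, n = 3) to no read at 10 days, at least 201-fold lower. All 4 were called in the mean of the 3 days (edgeR adjusted p = 1.7e-19 for MA_4984597g0010, 1.9e-13 for MA_186946g0010, 5.7e-14 for MA_10426531g0010 and 8.8e-20 for MA_175194g0010).

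With IAA the correlation across genes was 0.70 between 5 and 10 days, 0.86 between 10 and 15 days and 0.66 between 5 and 15 days. Of 9099 genes called at both 5 and 15 days, 94.4% had the same sign and 509 had opposite signs.

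Application of both hormones changed a near-constant number of genes, 16834 at 5 days, 17178 at 10 days and 17119 at 15 days. The rises and falls numbered 8175 and 8659 at 5 days, 8787 and 8391 at 10 days, and 8876 and 8243 at 15 days. Scaled by total counts, those at 5 days were 8481 and 8324. In the mean of the 3 days 12269 genes rose and 11775 fell. MA_459474g0010 and MA_73048g0010 had no read in any Mock library. In the combination MA_459474g0010 was at 29.3 ± 26, 274 ± 133 and 79.5 ± 55.8 CPM (SD, n = 3), at least 416-fold, 4210-fold and 1180-fold higher than Mock. Without replicate 1 at 5 days its limit was 216-fold (14.3 CPM), and without replicate 3 at 15 days 761-fold (49.4 CPM). MA_73048g0010 was at 24.9 ± 13.2, 223 ± 93 and 72.1 ± 15.4 CPM (SD, n = 3). At 10 days MA_459474g0010 was at 1 ± 0.83 CPM with IAA alone (0.585 CPM without replicate 3) and 0.067 ± 0.116 CPM with BAP alone, and MA_73048g0010 had no read with either (SD, n = 3). At 15 days BAP alone had 5.48 ± 6.75 CPM of MA_459474g0010 and 4.98 ± 5.77 CPM of MA_73048g0010 (SD, n = 3; 1.69 and 1.82 CPM without replicate 3), nearly all of it in replicates 1 and 3, with 52 and 203 reads of the first and 57 and 176 of the second (edgeR adjusted p = 0.011 and 0.041 against Mock). The interaction was not called at MA_459474g0010 or MA_73048g0010 on any day. At 5 and 10 days MA_73048g0010 had no read in Mock, BAP or IAA but 1192 and 10442 reads in the combination. With groups at the floor the interaction is poorly determined, so the missing calls do not show that the sum held. MA_158653g0010 had no read in any combination library, at least 565-fold, 657-fold and 603-fold below Mock on the 3 days. With BAP alone its mean was already 0.377, 0.0223 and 0.319 CPM, against 33.8, 42.6 and 40.3 CPM in Mock. With IAA alone it was 3.03, 19 and 15.1 CPM. MA_224931g0010 fell 11.1-fold at 5 days, from 115 ± 69.7 to 10.5 ± 6.76 CPM (SD, n = 3, and 6.96 CPM without replicate 2 of the combination). It had no read at 15 days, at least 2860-fold below Mock. With BAP alone it was at 5.73 ± 1.45 CPM at 5 days and 0.128 ± 0.169 CPM at 15 days (SD, n = 3). With IAA alone it was at 48.7 ± 26.8 and 60 ± 61.6 CPM (SD, n = 3). The edgeR adjusted p in the mean of the 3 days was 8e-11 for MA_459474g0010, 2e-06 for MA_73048g0010, 2.7e-16 for MA_158653g0010 and 5.5e-13 for MA_224931g0010. The correlation across genes between days was 0.79 (5 and 10 days), 0.83 (10 and 15 days) and 0.79 (5 and 15 days).

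**Figure D2:**
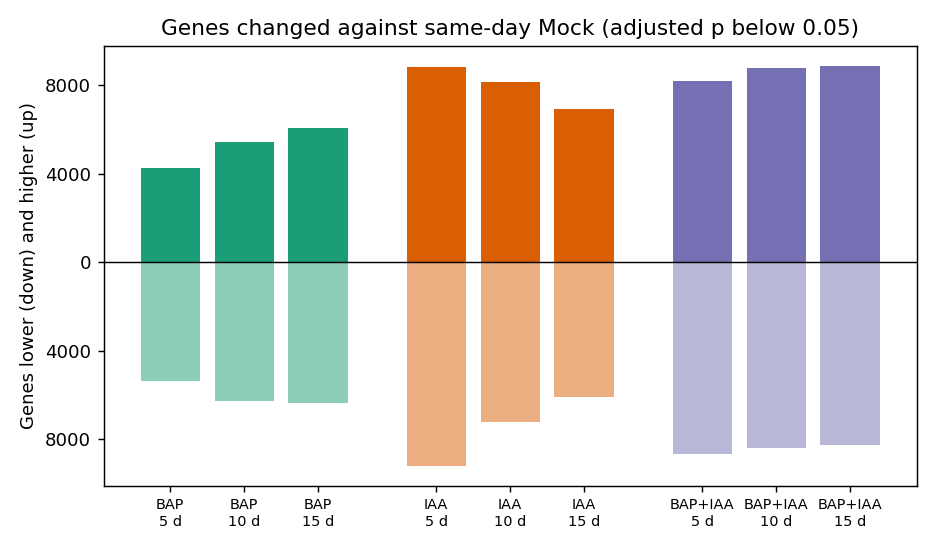
Bars give the number of genes (y axis) higher (up, full colour) and lower (down, pale) than same-day Mock at an adjusted p below 0.05, for each treatment and day (x axis), without error bars. IAA bars shrink from 18023 genes at 5 days to 13033 at 15 days and BAP bars grow from 9619 to 12400.

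Genes moved by both single hormones mostly moved the same way. At 5 days 2910 genes rose and 3655 fell with both BAP and IAA, and 575 moved in opposite directions. At 10 days 5931 genes moved the same way and 889 in opposite directions, and at 15 days 5989 and 676. Independent lists of those sizes would share 986 rising and 1286 falling genes at 5 days. Simulated unchanged groups with shared Mock libraries gave at most 1 gene called the same way in both. At most 3 genes were called for BAP and 1 for IAA in these simulations, so their overlap had to be small. They cannot show how much shared Mock noise adds to the overlap of long lists. The correlation across genes of the BAP and IAA changes was 0.47, 0.42 and 0.47 on the 3 days, against 0.51, 0.51 and 0.5 simulated with no effect. The covariance was 0.784, 0.832 and 1.05 against 0.123, 0.123 and 0.119 simulated, a difference of 0.661, 0.709 and 0.931. Each day has 3 Mock libraries, so a split would leave 1 of them on a side and was not made, and part of the excess may come from the shared controls. Contrasts of different days share no library, and in them 82 to 90.3% of the genes called in both had the same direction.

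Tested directly in the mean of the 3 days, 9314 genes were higher with BAP than with IAA and 10122 lower. The combination was above BAP at 8006 genes and below it at 7278. Against IAA it was above at 7447 genes and below at 7727. Scaled by total counts, 13216 genes were higher with BAP than with IAA and 7914 lower, with the median log2 difference of all genes at 0.14, and the combination was above BAP at 6426 genes and below it at 9413. It was then above IAA at 9070 genes and below it at 6842. Leaving out a single library also turned which side held more genes for the combination against BAP (7388 above and 7541 below without replicate 1 of the combination at 10 days, and likewise without 5 other combination libraries). It did so too for BAP in the mean of the 3 days (9594 and 8898 without replicate 1 of Mock at 15 days, 9484 and 8910 without replicate 3 of BAP at 10 days) and for IAA at 5 days (8408 and 8374 without its replicate 1). For the combination it did so at 5 days without its replicate 2 (8038 and 7359) or 3 (7527 and 6959), and at 10 days without replicate 1 (7731 and 7742) or 2 (7851 and 7951) of Mock.

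By direction in the mean of the 3 days, 5392 genes rose and 5932 fell with all 3 treatments. A further 2823 rose and 2505 fell with IAA and with the combination but were not called with BAP. Of those 2823 genes, 2222 were lower with BAP than with IAA in the direct test. Another 1819 rose and 1620 fell with BAP and with the combination without a call for IAA. Of the 1819, 1256 were higher with BAP than with IAA in the direct test. The genes called in the combination alone numbered 1541 higher and 993 lower, and 7907 genes were called in none. A missing call for BAP and IAA does not show that these genes answered to the combination only. On single days, few genes called in the combination but with neither hormone had an interaction called. They were 159 of 2569 at 5 days, 335 of 3557 at 10 days and 262 of 3804 at 15 days.

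The interaction asked whether the log2 change with both hormones equalled the sum of the single changes. At 5 days it was called at 6184 genes, at 10 days at 4944 and at 15 days at 4001. Of the 2910 genes that rose with both hormones at 5 days, 2007 were below the sum in the combination and 1 above it. Of the 3655 that fell with both, 1848 fell by less than the sum. At 10 days 952 of 2666 rising genes and 1109 of 3265 falling genes fell short of the sum, and at 15 days 960 of 2653 and 892 of 3336. Across genes called with BAP or IAA, the change in the combination followed the sum with slopes of 0.60, 0.52 and 0.60 (3 days). Slopes of the 3 single combination libraries, from log2 CPM with another prior count, had an SD of 0.018, 0.0091 and 0.017. BAP, IAA and Mock were held fixed in them, so this SD is not the spread of the slopes given. Noise in the single changes, which both contain Mock, can also lower a slope. A slope below 1 therefore does not by itself show a shortfall from the sum. Unchanged groups with shared Mock libraries gave a slope of 0.33, but over all tested genes. The observed slopes used only called genes, so 0.33 is not their expected value without an effect.

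Genes moved in opposite directions by the single hormones were followed in the combination. Of 335 genes raised by IAA and lowered by BAP at 5 days, 92 were higher than Mock in the combination and 49 lower. At 10 days 47 of 607 such genes were higher and 313 lower, and at 15 days 30 of 481 were higher and 271 lower. Among genes raised by BAP and lowered by IAA, the combination was higher at 44 of 240 and lower at 33 at 5 days, higher at 95 of 282 and lower at 22 at 10 days, and higher at 104 of 195 and lower at 8 at 15 days. The change of these counts with time was not itself tested.

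Part of the genes raised strongly by IAA fell short of the sum of the single changes in the combination. The 1030 genes raised at least 16-fold by IAA at 10 days had a median fold over Mock of 47.2 with IAA, 1.18 with BAP and 4.26 with both. The interaction was called lower at 416 of them (40.4%) and higher at 1, and 489 were called above Mock in the combination. At 10 days those 416 genes had a median fold over Mock of 42.6 with IAA, 4.19 with BAP and 6.88 with both. On days not used for the choice, these medians were 12.7, 1.39 and 5.44 (5 days) and 34.6, 4.02 and 8.59 (15 days). BAP alone thus also raised the median gene of this set at 10 and 15 days. At 5 days the medians of the 698 genes were 33.6 with IAA and 17.6 with both, 96 (13.8%) had an interaction called lower, and 514 were above Mock in the combination. At 15 days the medians of the 1077 genes were 40.8 and 6.58, 448 (41.6%) had one, and 618 were above Mock in the combination. The 416 genes took 6.29 ± 0.38% of the reads with IAA at 10 days, 1.56 ± 0.12% with both hormones, 0.875 ± 0.35% with BAP and 0.122 ± 0.034% with Mock (SD, n = 3), in the libraries on which they were chosen. On the days not used for the choice they took 2.72 ± 0.14% with IAA and 1.83 ± 0.19% with both hormones at 5 days, and 5.24 ± 0.27% and 1.69 ± 0.18% at 15 days (SD, n = 3).

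**Figure D3:**
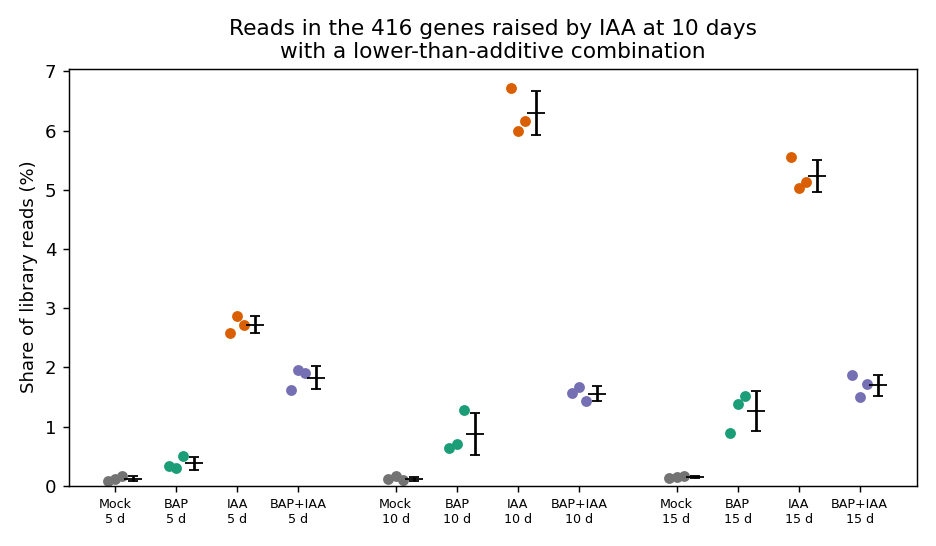
Share of all reads of a library (y axis, percent) in the 416 genes raised at least 16-fold by IAA at 10 days with an interaction called lower, by treatment and day (x axis). Points are libraries and black marks the mean and SD of 3. These genes were chosen on the 10-day libraries, where IAA libraries hold 6 to 6.72% and combination libraries 1.43 to 1.67%.

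The effect at 15 days was tested against that at 5 days for each treatment. The IAA effect differed between 15 and 5 days at 6201 genes, the combination effect at 2130 and the BAP effect at 675. Of the 6201 genes, 2353 were lower at 5 days and less so at 15 days, and 2154 were higher at 5 days and less so at 15 days. Another 633 were higher at 15 days without a call at 5 days, and 308 were lower. These classes use the 5-day libraries that also enter the difference, which favours effects that shrink. Genes called with IAA at 10 days share no library with it. Of the 8158 raised then, 1199 had a smaller and 793 a larger effect at 15 than at 5 days. Of the 7221 lowered then, 1263 had a smaller and 265 a larger effect. The median fold went from 1.68 to 1.58 for the rises and from 1.9 to 1.58 for the falls. Of the 675 genes of BAP, 226 were higher at 15 days without a call at 5 days and 199 were lower on both days and more so at 15 days. The BAP count rested on few libraries, with 321 genes without replicate 3 of BAP at 15 days, 413 without its replicate 2, 427 without replicate 1 of BAP at 5 days and 425 without replicate 3 of Mock at 15 days. With DESeq2 it was 1388, and with only the groups compared in the edgeR model 440.

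Mock hypocotyls were compared over the same days. At 15 days 605 genes were higher than at 5 days, by a median of 2.46-fold, and 355 lower, by a median of 2.17-fold. At 10 days 57 genes were higher than at 5 days and 41 lower. Both counts depended on the model and on single libraries. With only the groups compared in the edgeR model they were 463 (15 days) and 0 (10 days), the latter with 2976 genes at an unadjusted p under 0.05, and DESeq2 gave 1250 and 248. Without replicate 1 of Mock at 5 days they were 341 (15 days) and 12 (10 days), the latter with 1 gene higher and 11 lower. Without replicate 2 of Mock at 15 days the first was 407 and without its replicate 3 it was 639. The second was 57, with 23 higher and 34 lower, without replicate 2 of Mock at 5 days, 143, with 66 higher and 77 lower, without its replicate 3, and 13 and 34 without replicates 2 and 3 of Mock at 10 days.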

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

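The thinning test, the tests over other splits of the libraries and over permuted residuals, both tests of low counts, the contrast without Mock, the genes chosen on another day and the linear sum were chosen only after the data had been examined. Flagged here are differences between effects that were tested themselves. The effect at 15 days differed from that at 5 days at 6201 genes for IAA, 2130 for the combination and 675 for BAP, and the effect of one hormone depended on the other at 6184 genes at 5 days, 4944 at 10 days and 4001 at 15 days.

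Libraries were reassigned among the groups of a contrast within each day, in 33 splits with the real one included. As many genes as the real 6184, 4944 and 4001 came from 2, 5 and 8 of the 33 splits for the interaction, with highest other counts of 12772, 7932 and 7757. For the time differences, as many as the real 675, 6201 and 2130 came from 3, 7 and 5 of the 33 splits, with highest other counts of 5411, 13893 and 21481. Splits that call several times the real count point to a structure of the samples. Libraries of different treatments change places in them, so treatment effects enter the contrast, and these splits cannot by themselves exclude chance or measure it. The median of the other splits was 0 for 5 of the 6 counts and 259.5 for the interaction at 10 days.

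Chance was therefore also tested with the treatment effects kept in place. The residuals of a model without the tested contrast were permuted among the libraries of its groups, in 33 arrangements with the real one included, and limma counted the genes. For the interaction limma called 6769, 6039 and 4773 genes on the 3 days, and the highest other counts were 1521, 1634 and 1330. For the time differences it called 1074 genes for BAP, 6916 for IAA and 2470 for the combination, with highest other counts of 1, 1388 and 166. In each of the 6, 1 of 33 arrangements, the real one, gave as many genes. This argues against chance for these limma counts if residuals of different groups can be exchanged.

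The first pattern is that the IAA response differed between 5 and 15 days at more genes than the BAP response. Sequencing depth is argued against, since after thinning to equal depth the IAA count was still 9.3 times the BAP count. The size of that ratio is uncertain. Without thinning, leaving out 1 library gave 321 to 904 genes for BAP and 5068 to 5795 for IAA. Ageing shared by all treatments cancels in the contrast of the IAA and BAP time courses, which holds no Mock library and called 6940 genes. That contrast is the difference between the 2 effects, so it restates the pattern and is no separate test of ageing. A response that depends on seedling age cannot be told from days after application. Chance is argued against for each of the 2 counts by the permuted residuals, though not tested for their ratio, and a fading or changing auxin response stays open as an untested hypothesis. The pattern also rests on reading the collection numbers as 5, 10 and 15 days.

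The second pattern is that the combination moved genes by less than the sum of the log2 changes. Noise of shared Mock libraries is argued against, because 90.8% of the genes called the same way by both hormones at 10 days had an opposed interaction estimate at 5 days and 82.9% at 15 days, where no library was shared with the choice. Addition on the linear scale is argued against by the 78.2% of the rising genes whose 5-day level lay below the linear sum and the 71.5% at 15 days, although the median level was 0.798 of that sum at 5 days and 0.904 at 15 days. Of the rising genes, 87.8% had an opposed estimate at 5 days and 85.6% at 15 days. This argues against a floor met by falling levels as the only reason. Rising genes were not split by their Mock level, so low counts in Mock stay open for them. A limit to how far these genes can move may be a biological reason, and no test here bears on it.

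The third pattern is that 416 of the 1030 genes raised at least 16-fold by IAA at 10 days had an interaction called lower, while 489 of the 1030 were still called above Mock in the combination. One outside source of reads with a fixed profile is argued against, since the change from 5 to 10 days with IAA varied across the 416 genes 2.73 times as much as between 2 libraries of a group. Leaving out replicate 3 of BAP at 10 days left 75% of the genes called, exactly the bound set beforehand. At 15 days, in libraries not used to choose them, 324 of the 416 genes also had an interaction called lower. This argues against a deviation confined to 1 library of 10 days. Among BAP libraries, however, replicate 3 had the largest share of reads in these genes at 5, 10 and 15 days (0.508, 1.275 and 1.521%). A deviation tied to that replicate number would return at 15 days and stays open. Low counts were examined in a test that replaced one whose outcome the choice of genes had fixed. They are argued against by the 147 genes with a Mock level of at least 1 CPM. Of these, 87.1% had an interaction called lower (95% binomial interval over genes 80.6 to 92%). Low counts stay open for the 883 genes below 1 CPM, 32.6% of which had one (29.5 to 35.8%). Such intervals treat genes of the same libraries as independent, so they do not measure the spread between libraries. The genes were also chosen for a high ratio of IAA to Mock in libraries that enter the interaction, which favours lower estimates. A restraint of part of the auxin response by BAP is a candidate explanation. It remains a hypothesis, since loss of IAA from the combined preparation was not tested. BAP alone also raised the 416 genes, by a median of 4.19-fold at 10 days. The shortfall of genes raised by both hormones, the second pattern, was therefore not separated from it.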

How the results depend on the processing

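Thinning all libraries to equal depth and leaving out all libraries of a replicate number were chosen after the data had been examined. All 312 recomputed values of the named genes kept their direction and their side of the threshold, and 177 of 184 recomputed counts of changed genes, apart from left-out libraries, stayed within 1.5 times. Besides both Mock counts with the replicate block, given below, the exceptions were these. The BAP effect at 15 minus 5 days (675 genes) was 1388 with DESeq2 and 440 with only the groups compared. Mock at 10 against 5 days (98 genes) was 248 with DESeq2 and 0 with only the groups compared. Mock at 15 against 5 days (960 genes) was 463 with only the groups compared. That edgeR count of 0 stood beside 2976 genes at an unadjusted p under 0.05. With total counts as the scaling, the share of rises among the changed genes went from 48.5 to 59% for BAP in the mean of the 3 days and from 47.9 to 62.5% for BAP against IAA, where the TMM factors of the BAP libraries were the highest. Fitting fewer libraries leaves fewer degrees of freedom, and the cause of the other shifts was not tested.

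With the replicate number as a replicate block, Mock at 10 against 5 days gave 160 genes and Mock at 15 against 5 days 1528, and no other count moved by over 1.5 times. The labels do not say whether the numbers pair the libraries, so the main model, which leaves the number out, may pass over a pairing. Deviations from group means of libraries with the same number correlated at a mean of 0.0609 over 198 pairs (range -0.0867 to 0.28, 59 over 0.1), against -0.0303 for other numbers, and 23 of 36 libraries lay closest to their own number, a hint from the data only.

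Leaving out 1 library gave 321 to 904 genes for the BAP effect at 15 minus 5 days, 12 to 143 for Mock at 10 against 5 days and 341 to 924 for Mock at 15 against 5 days, the lowest without replicate 3 of BAP at 15 days and, for both Mock counts, replicate 1 of Mock at 5 days. Every other count of changed genes stayed within 1.5 times when 1 library was left out.

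Leaving out all libraries of 1 replicate number, which fits fewer samples, gave correlations between days of 0.588 to 0.65 (5 and 10 days), 0.621 to 0.724 (10 and 15 days) and 0.556 to 0.586 (5 and 15 days) for BAP, 0.648 to 0.691, 0.812 to 0.826 and 0.599 to 0.638 for IAA, and 0.738 to 0.768, 0.779 to 0.811 and 0.752 to 0.758 for the combination. The genes shared by BAP and IAA in the same direction then numbered 3699 to 4891, 3051 to 4484 and 3482 to 4449 on the 3 days, and in opposite directions 233 to 360, 370 to 567 and 320 to 378, with 1073 to 1296 opposite in the mean of the 3 days. The slope of the combination was 0.574 to 0.597, 0.501 to 0.505 and 0.557 to 0.598, with r = 0.812 to 0.84 at 10 days.

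With a mean of at least 1 CPM the correlations between days rose to 0.772 (5 and 10 days) and 0.695 (5 and 15 days) for BAP, 0.743, 0.893 (10 and 15 days) and 0.701 for IAA, and 0.83, 0.867 and 0.828 for the combination, and the slope of the combination on the sum to 0.546 at 10 days (r = 0.841) and 0.616 at 15 days. With a prior count of 2 the correlations were 0.781 and 0.691 for BAP, 0.876 (10 and 15 days) for IAA, and 0.82, 0.847 and 0.808 for the combination. At an adjusted p under 0.01, BAP and IAA shared 4198, 3545 and 3713 genes in the same direction on the 3 days and 256, 432 and 314 in opposite directions, with 1088 opposite in the mean of the 3 days and 11916 genes called in none. Contrasts of different days gave 4368 same and 959 opposite genes (BAP at 5, IAA at 10 days), 3935 same (BAP at 5, IAA at 15 days) and 1075 opposite (BAP at 15, IAA at 10 days). Other tests of gene lists were not run, since the files do not pair identifiers with names. Depth limits the low genes most, since 3 reads in a library are 0.13 to 0.24 CPM.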

Other observations

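The test of the place of the combination was chosen only after the result was seen. Each combination library was placed on the line from the same-day IAA mean (0) to the same-day BAP mean (1) over all tested genes. The places were 0.39 ± 0.062 at 5 days, 0.72 ± 0.015 at 10 days and 0.79 ± 0.06 at 15 days (SD, n = 3). All 3 libraries of 15 days lay nearer to BAP than all 3 of 5 days, a difference of 0.4 (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 libraries allow). A rising share of BAP in the response to both hormones is a candidate explanation. A change of the IAA or BAP response itself would move the ends of the line and was not separated from it.

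Other splits of the libraries were counted for the remaining contrasts. In the mean of the 3 days, 1 of 33 splits, the real one, gave as many genes in each of 6 contrasts. That is the smallest share that 33 splits allow, and libraries of different treatments change places in them too. Chance is argued against for each contrast but not excluded, and the replicates may be technical. The real and the highest other counts were 19084 and 6742 for BAP against Mock, 22411 and 2911 for IAA against Mock, 24044 and 10818 for the combination against Mock, 15284 and 2756 for the combination against BAP, 15174 and 2683 for the combination against IAA, and 19436 and 7180 for BAP against IAA. For the contrasts of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The highest other count was 2, 5 and 1 for BAP at 5, 10 and 15 days (real 9619, 11706 and 12400), 6, 0 and 6 for IAA (real 18023, 15379 and 13033), 2, 2 and 0 for the combination (real 16834, 17178 and 17119), and 4 and 3 for Mock at 10 and 15 days (real 98 and 960).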
